A study of Homo sapiens with 2 samples.

How the data were processed

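Total RNA of C4-2 cells, a human prostate cancer cell line, was profiled on Affymetrix oligonucleotide arrays. The cells had been transfected for 48 h with either miR-99a, a microRNA, or si-GL2, the small interfering RNA used as the control, whose name is that of a luciferase reporter siRNA. Each of the 2 groups holds 1 array, so no difference between the groups has a replicate and no p-value can be given.

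The authors deposited 1 signal intensity per probe set and array, on a linear scale, for 54675 probe sets. RNA was extracted with Trizol and labelled with biotin by the Affymetrix procedure, per the labels' protocols. The algorithm that summarised the probes into a probe set's intensity, its version, and the scaling of the arrays are not given in the sources used here. Detection calls and scanner files were not used here. The deposited intensity ran from 0.70 to 13495 on the miR-99a array and from 0.73 to 13399 on the si-GL2 array, with medians of 47.8 and 47.4. A probe set's precision is limited by the number of arrays.

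Signals were transformed to log2(signal + 16), and a difference is always miR-99a minus si-GL2 on this scale, which understates the change of dim genes. The array medians differed by 0.01 on this scale, below the limit of 0.1 set for centring, so the values were used as deposited. Gene names came from the platform annotation: 41091 probe sets carried 1 gene name, 1801 carried several, 62 were Affymetrix controls, and the other 11721 were left unnamed. Entrez identifiers of 41043 annotated probe sets were found in a reference gene table of GRCh38.p14, and 0 symbols had changed. Probe sets with several names or none stayed out of the gene comparison. Each of 19775 genes was represented by its brightest probe set, the one with the highest mean over both arrays. A gene counted as expressed when that mean reached the median of all probe sets, which corresponds to a signal of 47.2, and 12218 genes did. This limit is relative and is not a detection call.

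Genes were counted as higher or lower when they differed by at least 1.5-fold, a rule of size and not a test. Gene lists, 21 of pathways or cell states and 4 of markers of other cell types, were fixed before the data were examined, as were the size rule, the expression limit, the rule for named genes and the alternatives except those said to be added. A list's median difference was placed among 10000 random lists of the same size drawn from the expressed genes and matched on mean expression in 20 bins; the central 95% of the random medians is called the random range. This describes these 2 arrays and not the conditions, since genes of a pathway vary together between any 2 cultures. Lists with under 5 expressed members received values only. The miR-99a target list was written from memory of published and conserved predicted targets of the miR-99a and miR-100 family. The named genes are the 15 highest and 15 lowest expressed genes whose expressed probe sets all differ in the same direction, 18 genes fixed in advance, of which 2 are not analysed here, the 2 highest and 2 lowest members of each list, and, where said, genes chosen after their values were seen. Genes with only 1 expressed probe set, such as UGT2B28, DDC, TMEM100 and SLPI, passed the rule on direction without any check between probe sets. Other expressed members of the miR-99a target list are named as well, outside the rule fixed in advance.

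The list statistic was tested on simulated data built on the levels of the 12218 expressed genes, with 200 simulated lists of 30 genes. Differences were drawn independently for each gene, so the rates below do not cover lists whose members vary together. With 1000 random lists for each simulated list, 7% of lists with no shift fell outside the central 95%; all lists shifted by 0.3 were found (100%), and 76% of lists in which 10 members were shifted by 0.8. Of 200 genes changed 2-fold, 97% passed the 1.5-fold rule, as did 154 unchanged genes drawn with that spread. Alternatives were a 2-fold rule, centring on the median, quantile normalization, pseudocounts of 1 and 64, no expression limit, only genes above the 75th percentile of level, the mean over a gene's probe sets, and leaving out probe sets marked _x_ or _s_. The 75th percentile was taken over all probe sets, and 7738 genes lay above it. The mean over a gene's probe sets takes in those below the expression limit. Comparisons of genes with seed matches to miR-99a or to the si-GL2 guide strand had been planned and were not run, because no transcript sequences were used here. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.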

Results

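Genome-wide mRNA levels were measured in C4-2 prostate cancer cells 48 h after transfection with miR-99a and compared with cells that received the control siRNA si-GL2. C4-2 is an androgen receptor-positive line derived from LNCaP. Each condition was measured on 1 array, so all values below are single measurements, all differences are between 2 arrays, and neither a replicate error nor a p-value exists for them. The arrays were similar throughout, with a Pearson r of 0.988 across all 54675 probe sets on the log2 scale. The 18 probe sets of the hybridisation spikes, added equally to every array, differed by between -0.12 and 0.06, which gives the error of hybridisation and scaling alone.

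After miR-99a, 354 of 12218 expressed genes were at least 1.5-fold lower and 148 were at least 1.5-fold higher, while 95.9% lay within 1.5-fold. At 2-fold, 41 genes were lower and 17 higher. The SD of the log2 difference over expressed genes was 0.26 and the median was -0.03. A second expressed probe set, present for 5842 genes, served as a check within the arrays. Among 160 genes called lower by their brightest probe set, the second was lower in 137 and past 1.5-fold in 49. Among 54 genes called higher it was higher in 49 and past 1.5-fold in 27. Over all 5842 genes the second probe set was below 0 in 51.9%. This agreement concerns the arrays, not the variation between cultures.

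**Figure D1:**
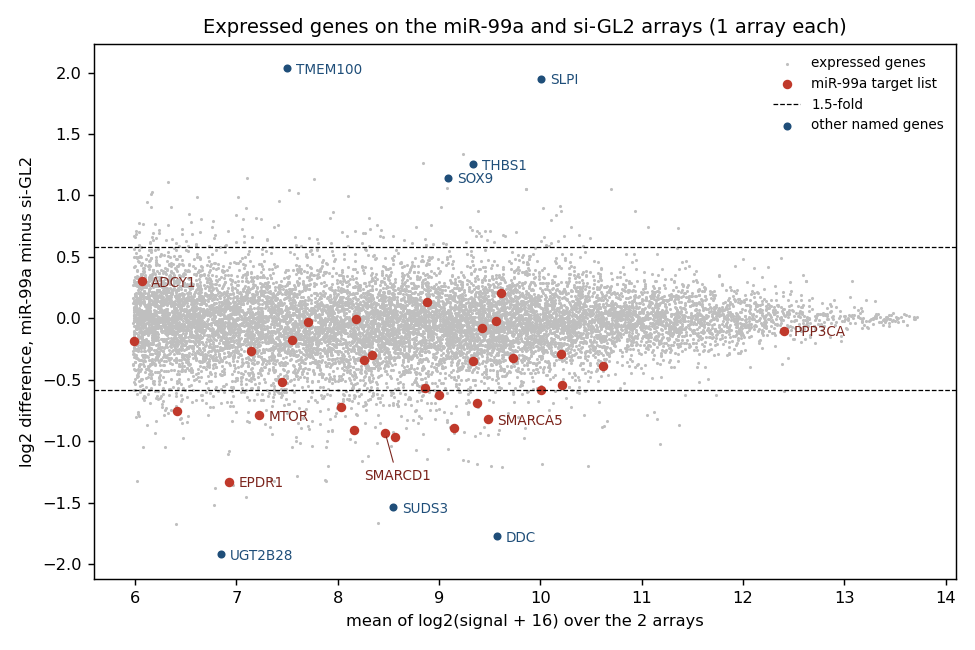
Difference between the miR-99a and si-GL2 arrays (log2, vertical axis) against mean level (log2, horizontal axis) for 12218 expressed genes (grey), with the miR-99a target list in red, other named genes in blue and dashed lines at 1.5-fold; 1 array per condition. Of the 32 target genes, 29 lie below 0 and 11 below the lower line.

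Genes on the list of miR-99a and miR-100 family targets were lower as a group. Of 32 expressed members, 29 lay below 0, 11 (34.4%) were at least 1.5-fold lower and 0 were 1.5-fold higher, against 2.90% and 1.21% of all expressed genes. The list's median log2 difference was -0.37, below all 10000 random lists (random range -0.14 to 0.05). EPDR1 was lowest on the list, with a signal of 60.9 after miR-99a and 177 after si-GL2, a difference of -1.33. PPFIA3 was at -0.97, the ubiquitin ligase ZNRF1 at -0.91 and the Wnt receptor FZD5 at -0.89. KBTBD8 (-0.75), the transcription factor GRHL1 (-0.72), the BMP receptor BMPR2 (-0.69) and RMND5A (-0.62) were also past 1.5-fold. RMND5A had another probe set of similar brightness at 506 against 482 (0.07), and a dimmer probe set at -0.38. TMEM30A, TTC39A, SLC44A1 and ZZEF1 were between -0.58 and -0.52 and did not reach 1.5-fold. As means over all their probe sets FZD5 was at -0.46, ZNRF1 at -0.45, GRHL1 at -0.50, BMPR2 at -0.42 and RMND5A at -0.31, short of 1.5-fold, while TMEM30A at -0.65 and RRAGD at -0.77 were past it. RRAGD was at -0.34 by its brightest probe set and at -1.19 by its second. SLC44A1 was at -0.30 on that averaging, TTC39A at -0.15 and ZZEF1 at 0.083. These averages take in probe sets below the expression limit. Those of ZZEF1 were at 13.4 against 1.3 and at 1 against 1, beside its expressed probe set at -0.52. Those of TTC39A were at 12.2 against 28.2 and at 15.7 against 2.81. The members above 0 were ADCY1 (0.30, or -0.069 as a mean over its probe sets), the Argonaute gene AGO2 (0.21) and PLK1 (0.13). The list was written from memory and is not a curated set, and 10 of its 32 expressed members are also on another list.

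The published work on this experiment pursued 3 members of the list, SMARCA5, SMARCD1 and MTOR, and these are therefore not independent evidence for the list's direction. SMARCA5, the ATPase of the ISWI chromatin remodelling complexes, was 522 after miR-99a against 934 after si-GL2, a difference of -0.82. Its 3 probe sets differed by between -0.94 and -0.79. SMARCD1, a subunit of the SWI/SNF complex, was 240 against 474 by its brightest probe set (-0.94), but its second, dimmer probe set was 82.4 against 65.3 (0.28). MTOR, the kinase of the mTOR complexes, was 97.9 against 181 (-0.79), with a second probe set below the expression limit at 40.6 against 34.0. As means over all their probe sets SMARCD1 was at -0.33 and MTOR at -0.30, short of 1.5-fold. Without these 3 genes the list's median was -0.34, and 8 of 29 members were 1.5-fold lower.

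Other genes fixed in advance as reported family targets differed less. The phosphatase gene CTDSPL was at -0.35, with its 3 expressed probe sets between -0.94 and -0.07. TRIB2 was at -0.29, or -0.17 as a mean over its probe sets, and RPTOR, the raptor subunit of mTOR complex 1, at -0.17. IGF1R was at -0.33 by its brightest probe set, at 0.39 by its second brightest and at 0.05 as a mean over all. PPP3CA (-0.10), FGFR3 (-0.03, or 0.14 as a mean over its probe sets) and BAZ2A (-0.00, or -0.14) differed by less than the probe set SD of 0.18. INSM1 was below the expression limit on both arrays, at signals of 5.03 and 17.2. The mTOR and PI3K-AKT pathway as a list, 35 members with a median of -0.08, lay inside its random range; 2 members were 1.5-fold lower, MTOR and PIK3CB (-0.59, or -0.56 as a mean over its probe sets, short of 1.5-fold), and AKT2 was highest at 0.35, or 0.17 on the same averaging. The 31 SWI/SNF and ISWI subunits had a median of 0.01 and a mean of -0.02, inside the range, with SMARCD1 and SMARCA5 the only members past 1.5-fold and RSF1 (0.42) and BAZ2B (0.39) highest.

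**Figure D2:**
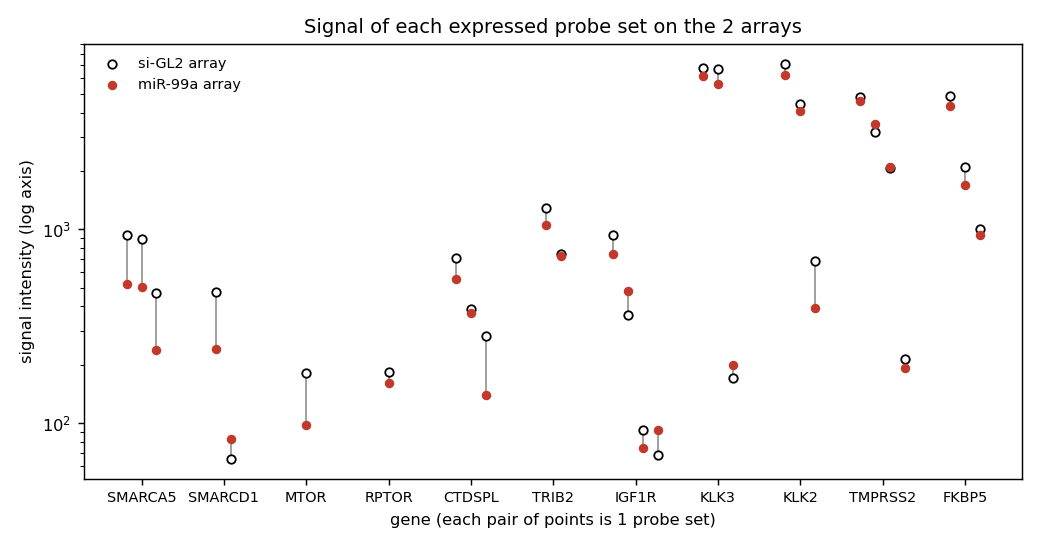
Signal intensity (log axis) of each expressed probe set on the miR-99a array (red) and the si-GL2 array (open) for family targets and androgen receptor target genes; a line joins the values of 1 probe set. All 3 probe sets of SMARCA5 are lower after miR-99a, whereas the probe sets of SMARCD1, IGF1R, KLK3 and TMPRSS2 disagree in direction.

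Androgen receptor target genes were slightly lower. The median over 29 expressed members was -0.08, just below the random range (-0.07 to 0.05); 18 lay below 0, 0 were 1.5-fold lower and 1 was 1.5-fold higher. KLK3, which encodes prostate-specific antigen, was 6180 after miR-99a against 6783 after si-GL2 by its brightest probe set (-0.13), 5616 against 6737 by the next (-0.26) and 200 against 171 by a dim one (0.20). KLK2 was at -0.20 by its brightest probe set, and its other 2 expressed probe sets were at -0.13 and, from 394 against 687, at -0.78. Its mean over all 4 probe sets was 0.00, which includes one below the expression limit at 22.7 against 1.87 (1.11). FKBP5 was at -0.17 and TMPRSS2 at -0.07 by their brightest probe sets, and the 4 probe sets of TMPRSS2 lay between -0.13 and 0.12. The lowest members were ACP3, prostatic acid phosphatase (-0.54), and ZBTB10 (-0.39), and the highest were STEAP4 (0.77) and KLK4 (0.25). As means over their probe sets ACP3 was at 0.06 and STEAP4 at 0.23. The list lay inside the random range when probe sets were averaged (median -0.047) and when _x_ and _s_ probe sets were left out (-0.026).

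The genes farthest below the control ranged from enzymes to regulators of transcription and RNA. UGT2B28, a glucuronosyltransferase, was 43.0 after miR-99a against 207 after si-GL2 (-1.92), measured by 1 probe set of a kind that can cross-hybridise with related genes. DDC, aromatic L-amino acid decarboxylase, was 396 against 1389 (-1.77). SUDS3, a subunit of the SIN3 histone deacetylase complex, was 203 against 620 (-1.54), and its other probe set was at -1.60. WWTR1, which encodes the Hippo pathway effector TAZ, was at -1.67, although its 3 probe sets ranged up to -0.09. INPP4B, a phosphoinositide phosphatase, was at -1.45, the anion exchanger SLC26A3 at -1.51 and the long non-coding RNA PSLNR at -1.67. The chemokine CXCL16 (-1.32), the chaperone DNAJB4 (-1.32), the ubiquitin ligase ZNRF2 (-1.35), KBTBD2 (-1.32), MYBPC1 (-1.38) and the RNA-binding protein CPEB3 (-1.31) followed. The kinase CDK6 was at -1.32 by its 1 expressed probe set of 7. As means over all their probe sets INPP4B was at -0.58 and CDK6 at -0.48, short of 1.5-fold. WWTR1 was then at -0.88, KBTBD2 at -0.81, DDC at -0.71, SLC26A3 at -0.70 and ZNRF2 at -0.64.

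Of the genes farthest above the control, TMEM100, a transmembrane protein, was 349 after miR-99a against 73.1 after si-GL2 (2.03). SLPI, a secreted protease inhibitor, was 2001 against 506 (1.95). The transcription factor SOX9 was 795 against 350.9 (1.15), with its second probe set at 1.09. THBS1, the matrix glycoprotein thrombospondin, was 979 against 401 (1.25), with 3 probe sets between 0.66 and 1.32. CDC42SE2 (1.34), the phosphatidylcholine transfer protein gene PCTP (1.26), PPP1R1B (1.14) and EMILIN3 (1.11) followed. CA13, EFR3A, CLDN12, ASS1, HLX and SLC52A3 were between 1.03 and 1.06. Of these, the tight junction gene CLDN12 had the highest signal, 2370 against 1137, and ASS1, argininosuccinate synthase, was 1322 against 630. RUNX2 was at 1.13 by its 1 expressed probe set of 6 and at 0.16 as a mean over all. On the same averaging CDC42SE2 was at 0.83, SLC52A3 at 0.69 and THBS1 at 0.68.

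**Figure D3:**
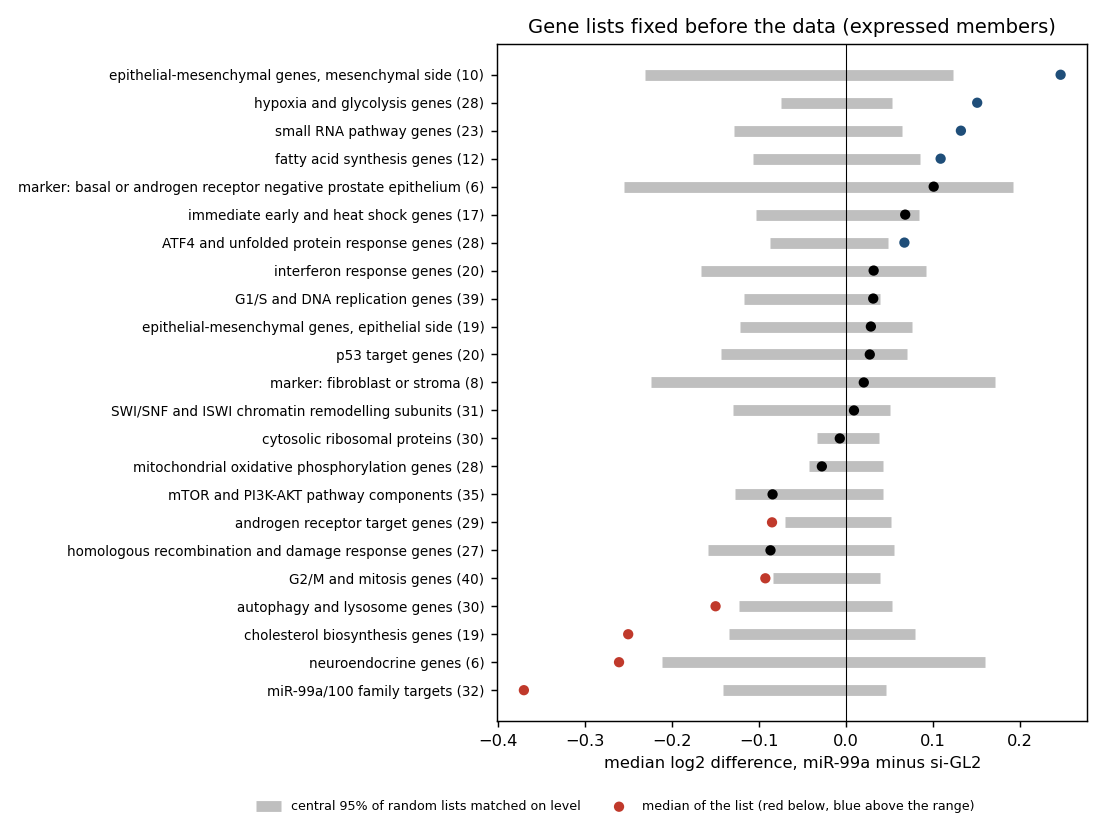
Median log2 difference, miR-99a minus si-GL2, of each gene list with at least 5 expressed members (points; number of members in parentheses) against the central 95% of 10000 random lists matched on level (grey bars). The miR-99a target list lies farthest below its bar at -0.37; hypoxia and glycolysis genes lie above theirs at 0.15.

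Of 23 lists with at least 5 expressed members, 6 had a median below the random range and 5 above it, where 1.15 would lie outside by chance if genes were independent. In 4 of these 11 lists the median stayed outside, on the same side, under all 9 alternatives that recomputed the lists. Centring, included in the 9, subtracts the same constant from every gene's difference and could not change a list's call. The 4 lists were the miR-99a targets, cholesterol biosynthesis, hypoxia and glycolysis, and the small RNA pathway. Cholesterol biosynthesis genes had a median of -0.25 over 19 members (random range -0.13 to 0.08). Of these, 14 lay below 0 and 0 passed 1.5-fold; the sterol isomerase gene EBP (-0.48) and squalene epoxidase, SQLE (-0.45, or -0.25 as a mean over its probe sets), were lowest, and SREBF2 (0.33) was highest by a probe set that another of its probe sets, at -0.62, contradicted. Hypoxia and glycolysis genes had a median of 0.15 over 28 members, above all random lists, with 24 members above 0. The glycolytic regulators PFKFB3 (1091 against 663, 0.70) and PFKFB4 (0.61) were past 1.5-fold, and SLC2A3 (-0.42, or 0.037 as a mean over its probe sets) and P4HA1 (-0.22, or -0.030) were lowest. Small RNA pathway genes had a median of 0.13 over 23 members, 18 of them above 0, led by the nuclear exporter XPO5 (0.41) and the decapping enzyme DCP2 (0.36). AGO4 (-0.60), the 1 member of that list past 1.5-fold, and TNRC6B (-0.54) went the other way; as means over their probe sets AGO4 was at -0.07, DCP2 at 0.21 and PFKFB4 at 0.32.

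The other lists outside the random range did not stay there under every alternative. The 10 expressed mesenchymal genes had a median of 0.25, with 9 above 0, and THBS1 and fibronectin, FN1 (0.59, or 0.45 as a mean over its probe sets), past 1.5-fold; LOX was at -0.45, or -0.19 on the same averaging. The 30 autophagy and lysosome genes had a median of -0.15, with the lysosomal channel MCOLN1 (-0.59) and the proton pump subunit ATP6V1H (-0.47) lowest and NPC1 (0.49) highest; as means over their probe sets ATP6V1H was at -0.29 and NPC1 at 0.18. The 40 G2/M and mitosis genes had a median of -0.09 with 0 past 1.5-fold; FOXM1 was at -0.34, NUSAP1 at -0.29, and MKI67 at 0.40. The 12 fatty acid synthesis genes had a median of 0.11, with FASN at 0.28 and ELOVL6 at -0.44, or 0.017 and -0.21 as means over their probe sets. The 28 ATF4 and unfolded protein response genes had a median of 0.07, and the cystine transporter SLC7A11 was the 1 member past 1.5-fold, at 0.90. The 6 expressed neuroendocrine genes had a median of -0.26, with DDC at -1.77 and UCHL1 at -0.53, or -0.71 and -0.28 as means over their probe sets.

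Lists inside the random range included the 39 G1/S and DNA replication genes (median 0.03), in which cyclin E1, CCNE1, was at 0.61 and the phosphatase CDC25A at -0.60; as means over their probe sets they were at 0.27 and -0.14. The 20 p53 target genes had a median of 0.03. AEN (0.81) and CDKN1A, which encodes p21 (883 against 534, 0.71), were past 1.5-fold and GADD45A was at -0.36. The 27 homologous recombination and damage response genes had a median of -0.09, with the replication protein RPA1 at 0.74 and BARD1 at -0.60, or -0.54 as a mean over its probe sets. The 20 interferon response genes had a median of 0.03 and a mean of -0.03, with BST2 at -0.69 and OASL at 0.43, or 0.13 as a mean over its probe sets. In the 17 immediate early and heat shock genes (median 0.07) EGR1 was at -0.73, from signals of 45.5 and 86.1, or -0.08 as a mean over its probe sets, and KLF4 at 0.33. This list lay above its range under 4 of the 9 alternatives, with medians between 0.082 and 0.10. The 30 ribosomal protein genes (median -0.01) and 28 oxidative phosphorylation genes (median -0.03) held 0 members past 1.5-fold by their brightest probe sets. For RPL38 that probe set was at -0.08, while its 3 probe sets ranged up to 0.64 and had a mean of 0.36. Epithelial genes had a median of 0.03 over 19 members, with CLDN7 at 0.35 and KRT19 at -0.41, or -0.11 as a mean over its probe sets, and lay above their range, at 0.14, when probe sets were averaged.

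Both marker lists of other cell types with enough expressed members lay inside their random ranges. The 8 expressed fibroblast or stroma markers had a median of 0.02, with LUM at 0.42 and THY1 at -0.46, from dim signals of 83.4 against 58.1 and of 45.5 against 68.3; as means over their probe sets they were at 0.15 and 0.0063. The 6 expressed basal epithelial markers had a median of 0.10, with EGFR at 0.49 (1424 against 1006), or 0.28 as a mean over its probe sets, and ITGA6 at 0.44. The leukocyte and endothelial lists each had 4 expressed members, between CSF1R at -0.27 and CD3E at 0.37, and between ROBO4 at -0.10, or 0.090 as a mean over its probe sets, and TIE1 at 0.55, or 0.38. The 3′ and 5′ control probe sets of ACTB and GAPDH, which reflect RNA integrity, were alike on both arrays: the log2 ratio of 5′ to 3′ signal differed by -0.02 for ACTB and 0.06 for GAPDH. The 5′ and middle control probe sets for 18S ribosomal RNA differed by a mean of -0.99 and the 3′ one by 0.09.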

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

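All tests of explanations in this part were chosen after the results were seen. Probe sets outside the gene comparison also held signal above the control array. Of 3770 unnamed probe sets above the expression limit, 6 were at least 2-fold higher after miR-99a, the highest by 1.61 on the log2 scale, and 6 were at least 2-fold lower. Of 1133 above the limit that the annotation gives to several genes, 1 was at least 2-fold higher, by 1.15, and 8 were lower.

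The first pattern is the lower level of the miR-99a target list, a median of -0.37 over 32 genes. A drift of the difference with signal level was argued against, since the median was -0.35 after a running median over level was removed, below the random range of -0.11 to 0.08. The random lists of the main comparison were already matched on level, so this removal is not a separate test of such a drift. Dependence on 1 odd probe set per gene was argued against too: the second-brightest probe sets of 19 members had a median of -0.29, below their random range of -0.15 to 0.12. The 3 genes pursued in the published work were not needed for the shift, as the other 29 members had a median of -0.34. Repression by the transfected miR-99a, the biological difference the design names, stays open and untested, because 1 array per condition cannot part it from any other difference between the 2 cultures or from effects of si-GL2.

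The second pattern is the excess of lower over higher genes, 354 against 148, or 70.5% of those past 1.5-fold. With the running median over level removed, 65.3% were lower (exact 95% binomial interval 60.8 to 69.6, over 464 genes treated as independent), so a drift with level does not account for all of the excess. Among the 7738 genes above the 75th percentile of level over all probe sets, 73.6% of those past 1.5-fold were lower (67.9 to 78.7). The excess was therefore not confined to dimmer genes. These changed genes are part of the same 354 and 148. Noise alike in both directions would give no excess at any level, so this is not a separate test of noise. An effect of miR-99a and a difference between the cultures unrelated to it both stay open.

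The third pattern lies in the control probe sets for 18S ribosomal RNA. Their 5′ and middle probe sets were 444 against 896 and 367 against 743, a mean difference of -0.99, whereas the 3′ probe set was 280 against 262 (0.09). More degraded RNA in the miR-99a sample was argued against by the ACTB and GAPDH controls, whose 5′ to 3′ ratios differed by a mean of 0.018, against a bound of -0.27 set from the 18S change. An equal difference in carry-over of both ribosomal RNAs was argued against by 2 probe sets for 28S, which differed by a mean of -0.24, less than the bound of -0.49 and more than the SD of 0.05 of the hybridisation spikes. A difference confined to priming or carry-over of 18S was not tested.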

How the results depend on the processing

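No paired analysis was possible because each condition has 1 array, and for the same reason no replicate could be left out. Alternatives that had not been planned, the removal of a running median over level and the target list without SMARCA5, SMARCD1 and MTOR, were added after the data were seen. The lower genes outnumbered the higher ones under every alternative, between 56.0% with no expression limit and 73.6% above the 75th percentile of level. Counts, higher then lower, moved by over 1.5 times from 148 and 354 to 17 and 41 under the 2-fold rule, to 74 and 179 with a pseudocount of 64, to 573 and 729 with no expression limit, to 73 and 203 above the 75th percentile, and to 91 and 206 with averaged probe sets. The rule, the limit and the pseudocount do this by construction. Averaging takes in probe sets below the expression limit, such as the second of DDC at 26.44 against 17.15, and left 10902 genes expressed. How much of the change in counts under averaging comes from this was not tested. The miR-99a target list stayed below its random range under all 9 recomputations, between -0.55 and -0.30, as did 3 other lists on their side. Centring, included in the 9, could not change these calls. Lists below the random range numbered 6 in the main setting, 2 with averaged probe sets and 3 without _x_ and _s_ probe sets; lists above it numbered 5, and 3 without those probe sets. Lists with under 5 expressed members had no value: neuroendocrine genes and both the fibroblast or stroma and the basal epithelial markers with averaged probe sets, without _x_ and _s_ probe sets and above the 75th percentile, and mesenchymal genes without _x_ and _s_ probe sets and above the 75th percentile. With averaged probe sets the medians of androgen receptor targets (-0.047), G2/M genes (-0.069), fatty acid synthesis (0.085), ATF4 and unfolded protein response genes (0.044) and autophagy and lysosome genes (-0.092) lay inside the range. Without _x_ and _s_ probe sets androgen receptor targets (-0.026), G2/M genes (-0.079) and ATF4 genes (0.066) did. Fatty acid synthesis (0.086) did so under quantile normalization, and mesenchymal (0.061) and neuroendocrine genes (-0.15) with no expression limit. In the other direction, immediate early and heat shock genes, inside the range in the main setting, lay above it under quantile normalization (0.0996), with no expression limit (0.082), above the 75th percentile (0.082) and with the running median removed (0.10), and epithelial genes with averaged probe sets (0.14). For these lists the cause was not tested. Of 1183 recomputed values of named genes, 130 moved by over 0.18, the SD of a probe set, and 34, from 25 genes, took the other sign; all 25 were under 1.5-fold in the main setting. The planned comparisons of miR-99a and si-GL2 seed matches were not run. Signals near the limit of 47.2 are the least certain, since the sources used here give no background level.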

Other observations

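The genes in this part were chosen after their values were seen, and no explanation is offered for them. CPEB4, a relative of CPEB3, was 301 after miR-99a against 687 after si-GL2 (-1.15), with 3 expressed probe sets between -1.15 and -0.71 and a mean over all its probe sets of -0.67. CPEB2 was at -0.14 by its brightest probe set and at -0.68 by a dimmer one, with a mean over all of -0.58. IGF1, insulin-like growth factor 1, was 668 against 1542 (-1.19), and its 4 expressed probe sets lay between -1.19 and -0.75, with a mean over all of -0.73. The proneural factor HES6 was at -1.16, TMEM41B was 921 against 2133 (-1.20), BLOC1S6 was 1613 against 3287 (-1.02), and KLF5 was at -0.51 and -0.68 by 2 probe sets.

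The chemokine gene CXCL12 was 223 after miR-99a against 107 after si-GL2 (0.95), with both probe sets above 0.86, and the interleukin receptor IL6R was 1588 against 834 (0.92), with 3 probe sets between 0.80 and 0.96. The adhesion receptor CXADR was 2638 against 1434 (0.87), with 4 probe sets between 0.68 and 1.01. The cytochrome gene CYP1B1 was at 0.86, with 3 expressed probe sets up to 1.16 and a mean over all of 0.47, and ENC1 was at 0.998 and 1.01. MIR99AHG, the host gene from which miR-99a itself is transcribed, was 982 against 950 (0.05, or 0.16 as a mean over its probe sets), and the luminal keratins KRT18 and KRT8 were both at 0.31.

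The 4 lowest log2 differences of all probe sets came from probe sets to which the annotation gives one and the same set of several genes, so they were left out of the gene comparison. Their signals after miR-99a and si-GL2 were 63.2 against 453 (-2.57), 184 against 926 (-2.24), 67.1 against 374 (-2.23) and 66.0 against 356 (-2.18). Which of those genes they measure is not resolved here.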
